A study of Mus musculus and Homo sapiens
Mus musculus with 13 samples.

How the data were processed

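RNA of the right hemisphere was measured in 13 mice of 3 groups, hCSF1-PBS (n = 5), hFIRE-PBS (n = 4) and hFIRE-HPC (n = 4), 1 library per mouse. Per the labels' protocols, mice were perfused with phosphate buffered saline, the hemisphere was frozen and crushed, RNA was extracted with an RNeasy Plus Micro kit, and 350 ng went into a TruSeq Stranded mRNA library sequenced as paired-end reads of 100 bases on a NovaSeq instrument. Selection was for polyadenylated RNA.

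The authors deposited expected counts per gene in a mouse table of 22310 genes covering all 13 mice and a human table of 20281 genes covering the 4 hFIRE-HPC mice. Per the submitters' processing notes, kallisto 0.46.1 and HISAT2 were used with the GRCm39 and GRCh38 genomes. The roles of the 2 aligners, the assignment of reads to species and the summing of transcripts to genes are not given in the sources used here, so reads of strongly conserved genes may have been placed in the other species. The authors also deposited a table of log2 values after a variance-stabilizing transformation (VST) for 13947 genes. Checking its columns against the counts showed that mouse and human columns were each transformed alone, with human values listed under mouse symbols, and that it does not add the 2 species, although its planned use had assumed that it did. The tool behind that transformation was not stated.

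Expected counts were rounded to whole numbers. Genes without a symbol held 0.0370 to 0.10 % of the counts and were left out. Per library 18128 to 18749 mouse genes were detected, and the 10 most abundant genes held 9.05 to 15.5 % of the counts. At a mean depth of 34.5 ± 4.99 M mouse counts (SD, n = 13), counting error is small beside the spread between mice for abundant genes. For genes of a few CPM it can be as large as that spread. Intervals on shares and ratios, and floors of 3 counts over a group, cover counting error only. Pairs of mice of one group differed by a chi-square per gene of 20.5 to 82.9 over genes with at least 20 counts, so no 2 libraries were alike within sampling noise.

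The 3 groups were taken from the labels and compared in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling, 1 model of the 13 mice with a mean per group, robust quasi-likelihood F tests, and Benjamini-Hochberg adjustment at 0.05 over the 16312 genes kept. All tests were two-sided. The median log2 change of all genes was -0.01, -0.00 and -0.00 in the 3 comparisons. Gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over 111 tests (37 lists and 3 comparisons), and again with an estimated correlation. At the preset, 50 of the 111 were called, with the estimate 5. The lists covered microglia, border-associated macrophages, monocytes and neutrophils, lymphocytes, disease-associated microglia, complement, MHC, interferon response, astrocytes, reactive astrocytes, myelin, oligodendrocyte precursors, disease-associated oligodendrocytes, cholesterol biosynthesis, cholesterol efflux and lysosome. Others held markers of excitatory and inhibitory neurons, synapse, axon injury, immediate early genes, endothelium, pericytes, fibroblasts, mineralisation, choroid plexus, ependyma, erythrocytes, striatum, thalamus, cerebellum, hypothalamus, dentate gyrus, olfactory bulb, mitochondrially encoded genes, cell cycle, and TGF-beta and CSF1 receptor ligands. Several lists share genes, complement and lysosome with microglia above all. For genes with 1 to 3 counts in a group, ratios with exact counting intervals replaced the fitted change for single genes. Genes without any count in a group had a bound from the floor of 3 counts. List medians with these genes at their bound were equal to 2 decimals. The procedure was tested on simulated data with known changes before use.

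Genes lower or higher in both hFIRE groups, and genes called in hFIRE-PBS mice and called in the reverse direction from hFIRE-PBS to hFIRE-HPC, were counted and set beside 40 simulations without differences. Human genes were described as CPM of human counts, with 10 counts in all 4 mice as the minimum. The human share is given with Clopper-Pearson intervals. VST values of the mouse columns were tested with limma (trend, robust). Human and mouse counts of microglia genes with the same symbol were added and compared by exact permutation. A pseudocount of 1 was set for the added values, but the reported means and ratios do not include it.

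The lists, tests, thresholds and alternatives were chosen before the data were examined, except the added human and mouse counts and the leaving out of mice for these and for human levels. Genes to be named were fixed by rule: among called genes with a mean of at least 1 CPM and no overlap between the 2 groups, the 10 largest changes in each direction, Csf1r, Csf1 and their human orthologs, up to 4 members of each list with the smallest p, the 10 most abundant human genes, and the 4 most abundant of each human list. Genes named outside this rule include members that alternatives or single mice moved, and those said to be chosen after their values were seen. Others are further list members, among them mouse Sall1 and Mertk and human TMEM119, SALL1, ISG15 and MRC1. Alternatives were DESeq2 1.42.0 (Wald test), voom with sample quality weights, DESeq2 size factors, no filter, a filter of 1 CPM in 4 mice, fits of 2 groups only, the replicate number as a block, stricter thresholds, fry in place of camera, and leaving out each mouse. A covariate for sex was planned only if both sexes occurred and was not run. Raw reads were not used here. Some genes that the rule names are not reported here.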

Results

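Gene counts were measured in the right brain hemisphere of 13 mice in 3 groups. hCSF1 mice, which carry the human CSF1 gene so that human myeloid cells can be supported, received phosphate buffered saline (hCSF1-PBS, n = 5). hCSF1-FIRE mice, which in addition lack an intronic enhancer of Csf1r and with it mouse microglia, received saline (hFIRE-PBS, n = 4) or human hematopoietic progenitor cells made from AICS-0036, an established induced pluripotent stem cell line (hFIRE-HPC, n = 4). Injections went into the ventricles and the cortex. Mouse counts totalled 35.9 ± 2.63 M per hCSF1-PBS library (SD, n = 5), 37.1 ± 6.08 M per hFIRE-PBS library (n = 4) and 30.1 ± 4.00 M per hFIRE-HPC library (n = 4), and ranged from 26.3 to 45.5 M over all 13. hFIRE-HPC libraries held a further 0.746 to 1.21 M human counts. Levels below are CPM, as mean ± SD over the mice of a group, in the order hCSF1-PBS, hFIRE-PBS, hFIRE-HPC (n = 5, 4 and 4). Mouse counts were scaled to the TMM-adjusted total of the tested mouse genes, and human counts to the human total. Fold changes are log2 values from edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over 16312 genes.

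The first comparison, hFIRE-PBS against hCSF1-PBS, asked what differed in the brain of mice without mouse microglia. The groups differ by genotype, so effects of lacking microglia cannot be told apart from any other difference between the genotypes. Csf1r, the receptor for CSF1 and IL34 whose enhancer is deleted in hFIRE mice, fell from 98.3 ± 15.3 to 1.38 ± 0.783 CPM, a log2 change of -6.19 (SE 0.308, edgeR adjusted p = 3.09e-08). Microglial genes fell almost throughout, and genes of border-associated macrophages, complement and lysosomal proteases fell in smaller numbers. A smaller set of genes rose, among them Akap12, Gpnmb and Klk6 and the oligodendrocyte genes Trf and Cldn11. Mouse Csf1, one ligand of the receptor, measured 0.599 ± 0.393 and 0.588 ± 0.192 CPM, a log2 change of -0.03 (edgeR adjusted p = 0.983). Human CSF1, which all groups carry, was counted only in hFIRE-HPC mice, so CSF1 of both species together was not compared. At an adjusted p below 0.05, edgeR called 98 genes higher and 307 lower in hFIRE-PBS mice.

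Of 40 tested members of the microglia list, 39 were called lower over all genes and 40 when adjusted over the list alone. Their median log2 change was -3.98, and the list was lower by camera with an estimated correlation (adjusted p = 5.21e-06). Siglech, a sialic acid receptor of microglia, fell from 14.5 to 0.0892 CPM (log2 -7.32, edgeR adjusted p = 7.41e-10). Gpr34, a lysophosphatidylserine receptor, fell by 7.25 (edgeR adjusted p = 4.04e-09), and P2ry13, an ADP receptor that sets resting motility, fell by 6.44 (edgeR adjusted p = 1.73e-08). P2ry12, the ADP receptor that draws microglial processes to injury, went from 37.1 ± 3.13 to 1.35 ± 0.276 CPM (log2 -4.79, SE 0.130, edgeR adjusted p = 1.47e-12). Cx3cr1, the fractalkine receptor, measured 54.8 ± 5.60 CPM in hCSF1-PBS mice and fell by 6.09 (edgeR adjusted p = 2.11e-08). Tmem119, a membrane protein restricted to microglia among brain cells, fell to 1.58 CPM (log2 -3.86, edgeR adjusted p = 1.73e-08). Clec5a, an activating lectin, and Ly86, a partner of a Toll-like receptor homologue, fell by 5.41 and 5.07 (edgeR adjusted p = 1.18e-06 and 7.16e-07). Sall1, a transcription factor of microglial identity that is also expressed in other neural cells, fell only from 34.1 to 21.4 CPM (log2 -0.67, edgeR adjusted p = 0.00085). Mertk, a phagocytic receptor that astrocytes also express, was the 1 member without a call (37.0 to 30.7 CPM, log2 -0.27, edgeR adjusted p = 0.279).

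**Figure D1:**
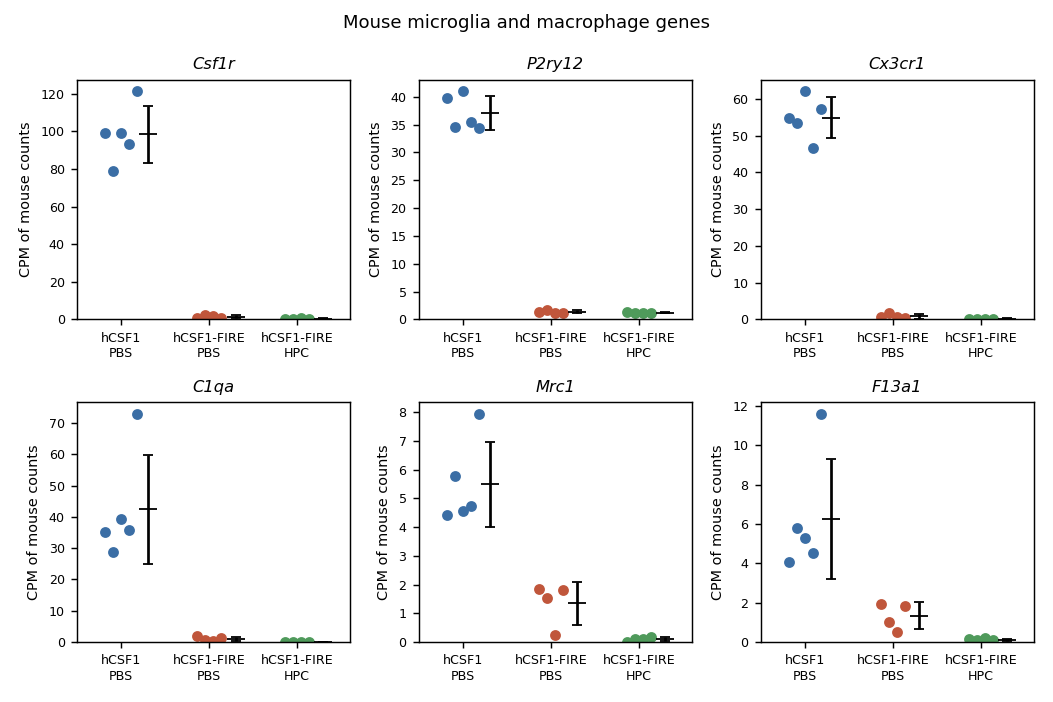
Levels of 6 mouse macrophage genes (vertical axis, CPM of mouse counts) in the 3 groups; points are mice, bars are mean ± SD. Csf1r, P2ry12, Cx3cr1 and C1qa lie near 0 in both hFIRE groups, whereas Mrc1 and F13a1 keep intermediate levels in hFIRE-PBS and not in hFIRE-HPC mice.

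Genes of border-associated macrophages, which line the meninges and vessels, had smaller changes than microglial genes. The median of 16 tested genes was -1.44, 7 were called lower (13 adjusted over the list alone), and camera gave an adjusted p of 7.34e-19. The list lay just above the threshold at an adjusted p = 0.0503 with an estimated correlation. Stab1, a scavenger receptor, fell from 17.8 ± 2.39 to 4.09 ± 0.528 CPM (log2 -2.12, edgeR adjusted p = 1.00e-07). F13a1, a coagulation transglutaminase of these cells, fell from 6.27 ± 3.07 to 1.32 ± 0.687 CPM (log2 -2.23, edgeR adjusted p = 0.00249). Pf4, a chemokine, fell from 1.22 to 0.196 CPM (edgeR adjusted p = 0.00443), and Lyve1, a hyaluronan receptor, fell by 2.13 (edgeR adjusted p = 0.00467).

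C1qa, C1qb and C1qc, which encode the initiating complex of the classical complement pathway, fell by 5.42, 5.25 and 5.13 (edgeR adjusted p = 1.58e-05, 7.04e-05 and 9.75e-06). The complement list had 5 of 17 members lower (8 adjusted over the list alone), a median of -0.45 and a camera adjusted p of 5.38e-10, but an adjusted p = 0.293 with an estimated correlation. C3ar1, the receptor of complement fragment C3a, fell from 3.07 to 0.229 CPM (log2 -3.81, edgeR adjusted p = 2.96e-05). Of the monocyte and neutrophil list, 1 of 12 members was called, Csf3r, the receptor of granulocyte colony-stimulating factor, which fell by 2.81 (edgeR adjusted p = 0.00429), and camera made no call (median -1.0, adjusted p = 0.140). Ly6c2, a marker of inflammatory monocytes, had a log2 change of -1.55 without a call (edgeR adjusted p = 0.159). Lymphocyte, MHC and antigen presentation, and interferon response lists had medians of -0.16, -0.43 and -0.59 and no called member. For interferon response genes camera at the preset correlation gave an adjusted p of 0.187. Without hCSF1-PBS mouse 5 the median turned to 0.27 (camera adjusted p = 0.0241, also at the preset). The estimated correlation of these genes was 0.786, with a camera adjusted p = 0.846 over all mice. It was not run without mouse 5, so whether that call would hold is not known.

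Genes tied to lipid-laden and disease-associated states of microglia divided. Gpnmb, a glycoprotein of lysosomes and of activated phagocytes, rose from 1.37 ± 0.599 to 7.28 ± 3.05 CPM although its usual microglial source was gone (log2 2.40, SE 0.326, edgeR adjusted p = 0.000278). Within the same list of 19 genes 2 members fell, Cd68, a lysosomal membrane protein of phagocytes, and Cd52, a surface glycoprotein of leukocytes (for Cd52, log2 -1.94, edgeR adjusted p = 0.0150, and 0.0679 without hFIRE-PBS mouse 4). The list median was -0.03, with no call by camera (adjusted p = 0.781). In the lysosome list 6 of 30 genes were called lower (10 adjusted over the list alone), with a median of -0.07 and a camera adjusted p of 2.69e-05, or an adjusted p = 0.402 with an estimated correlation. Ctss, the cysteine protease of antigen presenting cells, fell from 88.7 ± 43.9 to 2.68 ± 2.78 CPM (log2 -5.00, edgeR adjusted p = 0.000958). Cd68 and Man2b1, an alpha-mannosidase, fell by 1.68 and 0.64 (edgeR adjusted p = 9.20e-06 and 0.00279). Tgfb1, which microglia both make and need, and Tgfbr1, its receptor, fell by 1.39 and 1.31 (edgeR adjusted p = 0.000109 and 2.50e-06). Their list of TGF-beta and CSF1 receptor ligands had a median of -0.03 and 2 of 15 members called lower. Il34, the neuronal ligand of the same receptor, measured 42.0 and 51.3 CPM without a call (log2 0.29, edgeR adjusted p = 0.0691).

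In the myelin and mature oligodendrocyte list 28 of 29 members had positive changes, 6 were called higher (17 adjusted over the list alone), and the median was 0.36. Camera gave an adjusted p of 3.08e-13 with the preset correlation and an adjusted p = 0.263 with an estimated correlation. Trf, the iron carrier made by oligodendrocytes, rose from 239 ± 40.7 to 414 ± 19.9 CPM (log2 0.79, edgeR adjusted p = 0.000490). Cldn11, the tight junction protein of myelin, rose from 101 ± 15.7 to 155 ± 20.5 CPM (log2 0.62, edgeR adjusted p = 0.00538). Klk6, a protease of oligodendrocytes, rose from 3.98 ± 1.79 to 17.2 ± 6.91 CPM (log2 2.11, SE 0.315, edgeR adjusted p = 0.00139). Cholesterol synthesis, which supplies myelin, had a median of 0.21 over 24 genes, with 2 called higher (5 adjusted over the list alone) and a camera adjusted p of 1.54e-05, or an adjusted p = 0.454 with an estimated correlation. Sc5d, a late sterol desaturase, rose from 51.1 ± 2.96 to 69.3 ± 4.68 CPM (log2 0.44, edgeR adjusted p = 0.0114). The precursor and premyelinating list had a median of 0.14 and no called member. Its camera adjusted p of 0.0393 became an adjusted p = 0.540 with an estimated correlation, and 0.0977, 0.0621, 0.204 and 0.0634 without hCSF1-PBS mice 2 and 4 and hFIRE-PBS mice 3 and 4.

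Reactive astrocyte genes had a median of 0.31 with 1 of 22 called (5 adjusted over the list alone), S1pr3, a sphingosine phosphate receptor (log2 0.51, edgeR adjusted p = 0.0209). Leaving out hCSF1-PBS mice 4 or 5 or hFIRE-PBS mice 1 or 2 ended that call at adjusted p of 0.0554 to 0.0942. The list had a camera adjusted p of 0.00393, 0.0821 without hFIRE-PBS mouse 1, and an adjusted p = 0.540 with an estimated correlation. Gfap, the intermediate filament of reactive astrocytes, measured 402 ± 110 and 755 ± 185 CPM without a call (log2 0.91, edgeR adjusted p = 0.129). Col3a1, a fibrillar collagen, rose from 3.81 ± 0.619 to 6.29 ± 0.669 CPM (log2 0.72, SE 0.138, edgeR adjusted p = 0.00609). The fibroblast and extracellular matrix list held 2 called genes of 19 (6 adjusted over the list alone), a median of 0.26 and a camera adjusted p of 0.00304, or an adjusted p = 0.454 with an estimated correlation. For mineralisation and brain calcification genes, examined because calcification occurs when microglia are lacking, 1 of 19 was called, Gpnmb (4 higher adjusted over the list alone). That list had a median of 0.14 and a camera adjusted p of 0.00546, or an adjusted p = 0.0722 with an estimated correlation. Slc20a2, the phosphate importer mutated in familial brain calcification, measured 48.1 and 58.4 CPM (log2 0.28, edgeR adjusted p = 0.118).

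Neuronal and activity-induced lists held no called gene. Excitatory neuron, synapse, axon injury and immediate early gene lists had medians of 0.24, 0.14, 0.22 and 0.66, with camera adjusted p of 0.0161, 0.00893, 0.00138 and 0.000123. With an estimated correlation none of these calls held (adjusted p = 0.565, 0.565, 0.405 and 0.540). The excitatory call ended without hCSF1-PBS mouse 5 (0.0970) or hFIRE-PBS mice 2 and 4 (0.0643 and 0.0553), and the synapse call without hCSF1-PBS mouse 5 (0.0590) or hFIRE-PBS mouse 4 (0.0527). Slc17a7, the vesicular glutamate transporter of cortical neurons, measured 651 and 806 CPM (log2 0.31, edgeR adjusted p = 0.217), and Npas4, an activity-induced transcription factor, 14.1 and 48.7 ± 54.1 CPM (log2 1.79, edgeR adjusted p = 0.209). The choroid plexus, erythrocyte and mitochondrially encoded lists had medians of 0.35, -1.29 and -0.35, with 2 higher, 6 lower and 0 called adjusted over the list alone, and camera adjusted p of 0.00283, 0.00283 and 0.00234, none of them kept (adjusted p = 0.548, 0.463 and 0.579 with an estimated correlation). Camera made no call for inhibitory neuron (median 0.16), disease-associated oligodendrocyte (0.09), astrocyte (-0.03), ependymal (-0.30) or cell cycle genes (-0.02). Regional lists had medians of 0.08 for striatum, 0.03 for thalamus, -0.07 for cerebellum, 0.07 for hypothalamus and 0.17 for dentate gyrus, without a call. For the uncalled cholesterol efflux, endothelial, pericyte and olfactory bulb lists the medians were negative (-0.03, -0.05, -0.09 and -0.02) while the direction of the camera test was up, and the pericyte mean was positive (0.04).

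Among genes outside the lists, Akap12, a scaffold of protein kinase A, rose from 6.11 ± 0.504 to 28.2 ± 7.40 CPM (log2 2.20, SE 0.184, edgeR adjusted p = 1.63e-06). Eps8l1, an actin regulator, rose from 0.997 ± 0.201 to 3.45 ± 0.248 CPM (log2 1.79, edgeR adjusted p = 9.75e-06), and Alox8, an arachidonate lipoxygenase, rose by 1.46 (edgeR adjusted p = 0.00246). The largest rises among the genes named by the rule were those of Gm13304, Rec8 and Krt12, and several rises belonged to sparse or duplicated genes. Gm13304 and Gm10548, predicted genes with near-identical copies elsewhere in the genome, rose by 4.49 and 2.03 (edgeR adjusted p = 0.00893 and 0.00203), and reads could belong to another copy. Rec8, a meiotic cohesin, rose by 3.88 (edgeR adjusted p = 0.0134), and the call ended without hCSF1-PBS mice 4 (0.0503) and 5 (0.0581). Krt12, a corneal keratin, rose by 2.47 (edgeR adjusted p = 0.0327), with adjusted p of 0.0502 to 0.0992 without any one of the hCSF1-PBS mice, hFIRE-PBS mice 1, 2 and 4 or hFIRE-HPC mice 3 and 4. Pcdhga11, a clustered protocadherin that shares its constant exons with its neighbours, rose by 1.55 (edgeR adjusted p = 0.0273), with 0.0532 to 0.0833 without hCSF1-PBS mice 4 or 5 or any hFIRE-PBS mouse. The number of genes called higher also depended on single mice: 98 became 63, 226, 48 and 64 without hCSF1-PBS mice 2, 3, 4 and 5, and 63, 63 and 62 without hFIRE-PBS mice 1, 3 and 4.

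**Figure D2:**
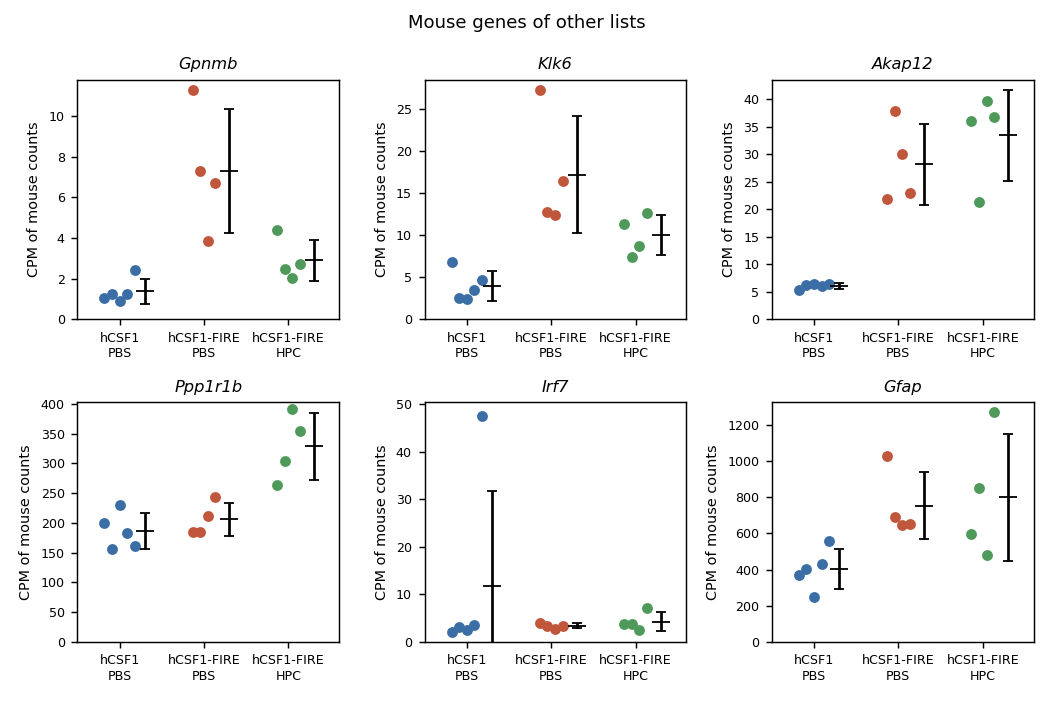
Levels (vertical axis, CPM of mouse counts) of Gpnmb, Klk6, Akap12, Ppp1r1b, Irf7 and Gfap in the 3 groups; points are mice, bars are mean ± SD. Gpnmb and Klk6 peak in hFIRE-PBS mice, Akap12 is high in both hFIRE groups, Ppp1r1b is highest in hFIRE-HPC mice and Irf7 stands out in 1 hCSF1-PBS mouse.

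The second comparison, hFIRE-HPC against hCSF1-PBS, asked which differences remained in the mouse transcriptome after human cells were given. Mouse microglial genes stayed low. Border-associated macrophage genes fell along nearly the whole list. Akap12, Cldn11, Trf and Klk6 were higher here as well, whereas Gpnmb and Col3a1 had no call, and edgeR called none of these 6 genes between the hFIRE groups. Of 14 striatal genes 7 were called higher, though not the list as a whole with an estimated correlation (camera adjusted p = 0.202). edgeR called 190 genes higher and 376 lower.

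Csf1r fell to 0.293 ± 0.192 CPM, a log2 change of -8.44 (SE 0.378, edgeR adjusted p = 8.75e-09). The microglia list had a median of -4.69, with 39 of 40 members lower both over all genes and adjusted over the list alone, and was lower by camera with an estimated correlation (adjusted p = 5.21e-06). P2ry12 fell to 1.22 ± 0.0799 CPM (log2 -4.92, edgeR adjusted p = 1.46e-12) and Cx3cr1 to 0.165 CPM (log2 -8.38, edgeR adjusted p = 6.85e-09). Tmem119 fell by 4.41 (edgeR adjusted p = 6.85e-09), Siglech by 7.36 (edgeR adjusted p = 1.16e-09) and Gpr34 by 8.81 (edgeR adjusted p = 3.34e-09). Itgam, the integrin chain CD11b, fell from 21.2 to 0.633 CPM (log2 -5.06, edgeR adjusted p = 1.16e-06). P2ry13 held 3 counts over the 4 mice, a 469-fold lower level (95% counting interval 160 to 2276), and Fcrls, a microglial Fc receptor-like gene, held none, at least 238-fold lower. In the border-associated macrophage list 15 of 16 members were called lower over all genes and over the list alone, with a median of -2.72 and an adjusted p = 0.0139 with an estimated correlation in camera. Mrc1, the mannose receptor, fell from 5.49 ± 1.48 to 0.0894 ± 0.0661 CPM (log2 -5.96, edgeR adjusted p = 1.83e-05) and F13a1 to 0.12 ± 0.0508 CPM (log2 -5.69, edgeR adjusted p = 3.78e-06). Stab1 fell by 2.53 (edgeR adjusted p = 1.76e-08), and Cd209g, a lectin of perivascular macrophages, by 4.49 (edgeR adjusted p = 7.88e-05).

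C1qb fell by 9.32 (edgeR adjusted p = 1.07e-05), C1qc fell from 38.2 to 0.0295 CPM (edgeR adjusted p = 1.13e-06), and C1qa was down to 1 count, a 5083-fold lower level (95% counting interval 912 to 200793). Of 17 complement genes 8 were lower and 1 higher (8 lower adjusted over the list alone), with a median of -0.61 and a camera adjusted p of 1.94e-15, or an adjusted p = 0.129 with an estimated correlation. The higher one was C4b, an acute-phase component made by astrocytes and oligodendrocytes, which rose from 91.0 to 204 ± 63.4 CPM (log2 1.16, edgeR adjusted p = 0.0279), with 0.0525 to 0.0865 without hCSF1-PBS mice 1, 2, 3 or 4 or hFIRE-HPC mice 2, 3 or 4. The lysosome list had 10 of 30 members lower (12 adjusted over the list alone), a median of -0.12 and a camera adjusted p of 3.21e-09, or an adjusted p = 0.171 with an estimated correlation. Ctss fell by 7.93 (edgeR adjusted p = 0.000156) and Ctsc, the protease that activates granule serine proteases, by 1.39 (edgeR adjusted p = 0.000543). Csf3r fell by 3.54 (edgeR adjusted p = 0.00101). Its monocyte and neutrophil list had a median of -0.90 and a camera adjusted p of 0.0334, or an adjusted p = 0.762 with an estimated correlation. That call ended without hCSF1-PBS mouse 5 (0.395, median 0.09) and hFIRE-HPC mice 1 (0.141) and 4 (0.0911). Tgfbr1 and Tgfb1 fell by 1.65 and 1.47 (edgeR adjusted p = 1.94e-07 and 5.47e-05). Disease-associated microglia genes had 3 of 19 members lower, a median of 0.07 against a mean of -0.59 and a downward test without a call (camera adjusted p = 0.146). The interferon response list had a median of -0.71 without a call (camera adjusted p = 0.136), MHC genes -0.36 and lymphocyte genes -0.18, the last with a mean of 0.02 and an upward test.

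The myelin list had 28 of 29 positive changes, a median of 0.28, and 3 called genes (4 adjusted over the list alone). Camera gave an adjusted p of 5.79e-06 and an adjusted p = 0.527 with an estimated correlation. Cldn11 rose to 151 ± 10.4 CPM (log2 0.58, edgeR adjusted p = 0.00737) and Trf to 345 ± 37.6 CPM (log2 0.53, edgeR adjusted p = 0.0144, and 0.0631 without hFIRE-HPC mouse 4). Klk6 rose by 1.32 (edgeR adjusted p = 0.0369), with 0.0533 to 0.110 without hCSF1-PBS mice 2, 3, 4 or 5, hFIRE-PBS mouse 4 or hFIRE-HPC mice 1, 3 or 4. Sc5d rose by 0.47 (edgeR adjusted p = 0.00542) as the only called gene of cholesterol biosynthesis (1 adjusted over the list alone). Its list had a median of 0.11 and a camera adjusted p of 0.0255, or an adjusted p = 0.711 with an estimated correlation. That list call ended without hCSF1-PBS mice 2 and 3 (0.0983 and 0.0502) and hFIRE-HPC mice 1 and 4 (0.159 and 0.0830). Disease-associated oligodendrocyte genes had a median of 0.07, 2 of 16 called, and a camera adjusted p of 0.0313, or an adjusted p = 0.519 with an estimated correlation. Without hCSF1-PBS mice 2, 3 and 4 the adjusted p was 0.0509, 0.0617 and 0.0613. Gpnmb fell short of a call at 2.90 ± 1.02 CPM (log2 1.08, edgeR adjusted p = 0.0988), as did Gfap at 800 ± 353 CPM (log2 0.99, edgeR adjusted p = 0.0795). Col3a1 measured 3.74 ± 0.235 CPM, near its hCSF1-PBS level.

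All 14 tested genes of striatal neurons had positive changes, 7 were called higher (12 adjusted over the list alone), and the median was 0.65. Camera gave an adjusted p of 3.08e-13, or an adjusted p = 0.202 with an estimated correlation. Ppp1r1b, the dopamine-regulated phosphatase inhibitor of spiny projection neurons, rose from 186 ± 30.4 to 329 ± 55.7 CPM (log2 0.82, SE 0.134, edgeR adjusted p = 0.00133). Penk, the enkephalin precursor, rose from 114 ± 26.7 to 219 ± 16.0 CPM (log2 0.94, edgeR adjusted p = 0.00157). Adora2a, the adenosine receptor of the indirect pathway, rose by 0.88 (edgeR adjusted p = 0.0271), with 0.0553 to 0.0959 without hCSF1-PBS mice 4 or 5 or hFIRE-HPC mice 2, 3 or 4. Excitatory neuron, inhibitory neuron, synapse and axon injury lists had medians of 0.17, 0.22, 0.16 and 0.22 and camera adjusted p of 0.00152, 0.00152, 0.00864 and 0.00147. None held with an estimated correlation (adjusted p = 0.519, 0.252, 0.565 and 0.405), and the synapse call ended without hCSF1-PBS mouse 5 (0.0557) and hFIRE-HPC mice 2 and 3 (0.0936 and 0.0656). Nrgn, a postsynaptic calmodulin-binding protein, rose from 567 to 804 CPM (log2 0.50, edgeR adjusted p = 0.0279), with 0.0502 to 0.0964 without hCSF1-PBS mice 2, 4 or 5 or hFIRE-HPC mice 3 or 4.

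In the remaining lists few genes were called. Erythrocyte genes had a median of -1.57, 1 of 8 lower, Hbb-bs, a globin with near-identical copies (5 adjusted over the list alone) and a camera adjusted p of 0.00116, or an adjusted p = 0.454 with an estimated correlation. Choroid plexus genes had a median of 0.25 (camera adjusted p = 0.0476) and immediate early genes 0.47 (camera adjusted p = 0.0251), with an adjusted p = 0.758 and 0.762 with an estimated correlation. The choroid plexus call ended without hCSF1-PBS mice 2, 3 or 4, hFIRE-PBS mice 2, 3 or 4 or hFIRE-HPC mouse 3 (0.0527 to 0.261), and the immediate early call without hCSF1-PBS mice 4 and 5 (0.0919 and 0.0849) and hFIRE-HPC mice 1 and 3 (0.0970 and 0.248). Medians without a camera call were -0.09 for fibroblast, 0.08 for reactive astrocyte, 0.08 for mineralisation, -0.21 for mitochondrially encoded, 0.16 for pericyte and -0.06 for endothelial genes. Regional lists other than striatum had medians of -0.12 for thalamus, 0.08 for hypothalamus and 0.07 for dentate gyrus. Cerebellum and olfactory bulb medians of 0.00 and 0.04 stood beside means of -0.07 and -0.04 and upward tests, all without a call. Outside the lists, Akap12 rose by 2.45 (edgeR adjusted p = 4.32e-07), Alox12b, a skin lipoxygenase, by 1.65 (edgeR adjusted p = 0.000685), and Thbs4, a thrombospondin of astrocytes, by 1.50 (edgeR adjusted p = 0.00665). Kcnj14, an inwardly rectifying potassium channel, rose from 2.43 to 6.38 CPM (log2 1.39, edgeR adjusted p = 0.00136), and Eps8l1 rose by 1.06 (edgeR adjusted p = 0.00222). Mroh5, a HEAT-repeat gene without an assigned function, rose by 1.45 (edgeR adjusted p = 0.0220), with 0.0563 to 0.0725 without hCSF1-PBS mice 1 or 4 or hFIRE-HPC mice 1, 3 or 4. Hmga1, a chromatin protein with many processed pseudogenes that may share its reads, rose from 19.7 to 51.8 CPM (edgeR adjusted p = 0.0486), with 0.0597 to 0.131 without any one mouse but hCSF1-PBS mouse 2 and hFIRE-PBS mouse 3. The 190 higher genes became 114, 104, 102 and 92 without hCSF1-PBS mice 1, 2, 4 and 5, and 91 and 116 without hFIRE-HPC mice 3 and 4.

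The third comparison, hFIRE-HPC against hFIRE-PBS, asked whether human cells returned any mouse gene toward the hCSF1-PBS level. No gene passed the test in either direction. As groups, mouse microglia genes and fibroblast and extracellular matrix genes were lower in hFIRE-HPC mice, both narrowly (camera adjusted p = 0.0498 for each with an estimated correlation). Border-associated macrophage genes lay lower and striatal genes higher at the preset correlation of camera, and narrowly missed the threshold with an estimated correlation (adjusted p = 0.0503 for each). edgeR called 0 genes higher and 0 lower (350 and 390 at an unadjusted p below 0.05, smallest adjusted p 0.206), voom called 0 and 0, and DESeq2 called 10 and 26. In a single simulated data set for this comparison 26 of 183 DESeq2 calls were false, against 7 of 151 for edgeR. DESeq2 recovered 78.5 % of the changed genes it tested and edgeR 73.5 %. Those data were drawn with edgeR's own estimates of the spread, so they cannot decide between the tools.

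Mouse microglia genes had a median of -0.53 with 32 of 40 negative, 16 lower adjusted over the list alone, and camera with an estimated correlation gave an adjusted p = 0.0498. Csf1r had a log2 change of -2.25 (SE 0.476, edgeR adjusted p = 0.293, DESeq2 adjusted p = 0.00252), and C1qa, at 1 count, was 121-fold lower (95% counting interval 21.4 to 4819). In the border-associated macrophage list 15 of 16 genes had negative changes, the median was -1.07, and 8 were lower adjusted over the list alone. Camera gave an adjusted p of 6.51e-20 and an adjusted p = 0.0503 with an estimated correlation. Mrc1 had a log2 change of -3.94 (edgeR adjusted p = 0.206, DESeq2 adjusted p = 2.26e-06) and F13a1 of -3.45 (edgeR adjusted p = 0.206, DESeq2 adjusted p = 3.00e-06). Cd209f, a lectin of border macrophages, at 1 count, was 57.8-fold lower (95% counting interval 10.1 to 2315). Without hCSF1-PBS mouse 5 edgeR called F13a1 lower (adjusted p = 0.0221). Without hFIRE-PBS mouse 3 it called 7 genes lower: C1qa (adjusted p = 0.0493), Fcrls (0.0121), Cd209f (0.0121), C1qc (0.0121), Cd209b (0.0179), Mrc1 (0.000937) and F13a1 (0.00910). Complement genes had a median of -0.26, 4 lower adjusted over the list alone and a camera adjusted p of 2.22e-08, or an adjusted p = 0.30 with an estimated correlation.

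Fibroblast and extracellular matrix genes had a median of -0.36 with 15 of 19 negative, 9 lower adjusted over the list alone, and camera gave an adjusted p of 5.42e-12, and an adjusted p = 0.0498 with an estimated correlation. Col3a1 had a log2 change of -0.75 (edgeR adjusted p = 0.223, DESeq2 adjusted p = 0.00303), and Bgn, a small matrix proteoglycan, of -0.36 (edgeR adjusted p = 0.345, DESeq2 adjusted p = 0.0285). Striatal genes had a median of 0.55, 14 of 14 positive, 12 higher adjusted over the list alone and a camera adjusted p of 1.16e-25, or an adjusted p = 0.0503 with an estimated correlation. Ppp1r1b had a log2 change of 0.67 (edgeR adjusted p = 0.236, DESeq2 adjusted p = 0.00728). Gpnmb and Klk6 had changes of -1.33 and -0.79 without a call (edgeR adjusted p = 0.455 and 0.999), and Akap12 measured 33.4 ± 8.25 CPM against 28.2 ± 7.40 in hFIRE-PBS mice. Myelin genes had a median of -0.12 (camera adjusted p = 0.000329), cholesterol biosynthesis -0.08 (0.00393), lysosome -0.07 (0.00194), mineralisation -0.08 (0.00267) and reactive astrocyte -0.27 (0.0112). With an estimated correlation these gave camera adjusted p = 0.565, 0.565, 0.527, 0.0503 and 0.565. Single mice ended the myelin call (hFIRE-PBS mouse 3, 0.103; hFIRE-HPC mouse 2, 0.228), the cholesterol call (hFIRE-PBS mouse 1, 0.0962; hFIRE-HPC mouse 2, 0.400), the mineralisation call (hFIRE-HPC mouse 2, 0.0601) and the reactive astrocyte call (hFIRE-PBS mouse 1, 0.662; hFIRE-HPC mouse 3, 0.242).

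The remaining camera calls between the hFIRE groups were weak. Disease-associated microglia genes had a median of -0.08 (camera adjusted p = 0.0287), precursor and premyelinating genes -0.10 (0.0334), inhibitory neuron genes 0.08 (0.0255), immediate early genes -0.27 (0.0334) and endothelial genes -0.16 (0.0221). Thalamus genes had a median of -0.17 (camera adjusted p = 0.0293) and mitochondrially encoded genes 0.14 (0.0313). With an estimated correlation the camera adjusted p of these lists was 0.633, 0.540, 0.462, 0.782, 0.548, 0.762 and 0.762. Every one of these calls ended when single mice were left out. Without hFIRE-PBS mouse 1 the adjusted p was 0.565 for disease-associated microglia, 0.201 for endothelial, 0.400 for mitochondrially encoded and 0.0687 for thalamus genes. Without hFIRE-PBS mouse 2 it was 0.106 for inhibitory neuron genes. Without hFIRE-PBS mouse 3 it was 0.375 for precursor, 0.0672 for inhibitory neuron, 0.743 for immediate early, 0.153 for mitochondrially encoded and 0.316 for thalamus genes. Without hFIRE-PBS mouse 4 it was 0.10 for precursor and 0.141 for immediate early genes. hFIRE-HPC mouse 1 ended the precursor (0.0774) and mitochondrially encoded calls (0.290). hFIRE-HPC mouse 2 ended the disease-associated microglia (0.291), precursor (0.25), inhibitory neuron (0.322), immediate early (0.234), endothelial (0.112) and thalamus calls (0.229). hFIRE-HPC mouse 3 ended the mitochondrially encoded (0.113) and thalamus calls (0.131), and hFIRE-HPC mouse 4 the immediate early (0.929), endothelial (0.0525) and thalamus calls (0.0503). In the uncalled cholesterol efflux, axon injury and pericyte lists the medians of -0.01, -0.06 and -0.01 stood beside positive means of 0.11, 0.10 and 0.09, and in the olfactory bulb list a median of 0.11 beside a downward test.

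Across the 2 comparisons with hCSF1-PBS mice, 51 genes were higher and 257 lower in both hFIRE groups, 308 in all. Independence would give 1.14 and 7.08, and 40 simulations without any difference gave 0. The simulations drew each gene on its own, so they hold no genes that vary together. Because the same hCSF1-PBS mice enter both comparisons, their log2 changes covary without any effect: the covariance was 0.244 (r = 0.818) against 0.0263 (r = 0.435) in the simulations. When hCSF1-PBS mice 1, 2 and 3 served for one comparison and mice 4 and 5 for the other, 203 genes were called in both, and 235 in the reverse. Without hCSF1-PBS mouse 5 the number was 248. Genes called in hFIRE-PBS mice and called in the opposite direction between hFIRE-HPC and hFIRE-PBS mice numbered 0 by edgeR and 0 in the simulations. DESeq2 gave 4: Col3a1 and Bgn, up in hFIRE-PBS and lower in hFIRE-HPC mice, and Cyp4f15, a fatty acid hydroxylase, and Ankrd37, a hypoxia-induced gene, in the reverse directions. Of the 98 genes higher in hFIRE-PBS mice, 77 had negative changes from hFIRE-PBS to hFIRE-HPC (median -0.11) and 97 kept a positive change against hCSF1-PBS mice. Shared use of the hFIRE-PBS mice alone would tie those signs, and the covariance of the 2 sets of changes was 0.00373 against -0.0339 simulated. Of the 307 lower genes, 113 had the opposite sign (median -0.12) and all 307 stayed below hCSF1-PBS.

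Human counts described the cells that took the place of mouse microglia. They made up 2.58 (95% counting interval 2.58 to 2.59), 2.98 (2.98 to 2.99), 2.69 (2.68 to 2.69) and 4.38 (4.38 to 4.39) % of all counts in hFIRE-HPC mice 1 to 4, a mean of 3.16 ± 0.834 % (n = 4). At least 10 counts in all 4 mice were found for 8052 of 20281 human genes, among them all 27 microglia genes, whose median per mouse was 872, 764, 732 and 887 CPM of human counts. CSF1R measured 3694 ± 557 CPM, P2RY12 3627 ± 1143, CX3CR1 3686 ± 863, TMEM119 498 ± 92.2 and SALL1, the identity factor, 509 ± 116 CPM. The most abundant transcripts were MT-CO1 (13424 ± 1477 CPM), EEF1A1 (12230 ± 2853), FTL (9250 ± 1148), ACTB (7798 ± 2237) and SPP1 (7776 ± 4546), the last a secreted phosphoprotein of activated microglia. C3, the central complement component that human microglia express strongly, measured 7683 ± 1122 CPM. Among disease-associated microglia genes 17 of 20 were detected (median 288 CPM), with APOE, a lipid carrier, at 2317 ± 1045 CPM. All 11 MHC genes were found (median 608 CPM), among them CD74, the invariant chain, at 3521 ± 1951 CPM. Of the border-associated macrophage list 8 of 9 were found (median 165 CPM), with LYVE1 at 435 ± 316 and MRC1 at 168 ± 94.8 CPM. Of other lists, fewer genes reached 10 counts in all 4 mice: 3 of 11 monocyte and neutrophil genes, 2 of 11 progenitor genes, 1 of 10 lymphocyte genes (CD4, which microglia also express), 1 of 13 neuron and macroglia genes (MBP, 83.0 CPM), 2 of 8 cell cycle genes and 0 of 7 pluripotency genes. Cell cycle genes differed between mice, with medians of 3.39, 17.5, 8.04 and 48.9 CPM in hFIRE-HPC mice 1 to 4. CSF1 counts of 706 ± 170 CPM can come from the human CSF1 allele of the mice or from the human cells, which these data cannot separate.

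Interferon response genes differed widely between the 4 mice with human cells. The median of that list, with 11 of 13 genes detected, was 37.3, 581, 64.3 and 711 CPM in hFIRE-HPC mice 1 to 4. CXCL10, a chemokine for T cells, measured 29.4, 1025, 6.70 and 1454 CPM, and ISG15, a ubiquitin-like antiviral protein, 22.6, 487, 20.1 and 559 CPM. IFI44L measured 37.3, 1142, 189 and 1043 CPM. SPP1 measured 5301, 11581, 2609 and 11611 CPM, whereas C3 and CSF1R varied little. Without uninjected human cells for comparison, these values describe each mouse and were not tested.

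**Figure D3:**
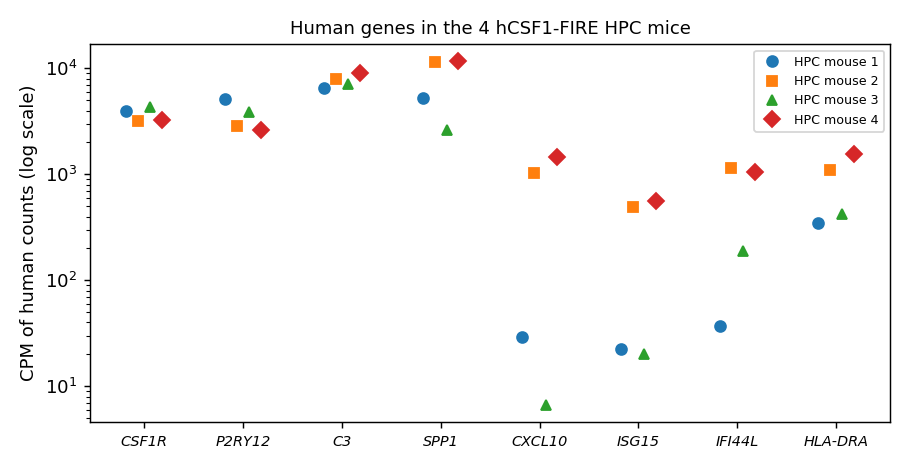
Levels of 8 human genes (vertical axis, CPM of human counts, log scale) in each hFIRE-HPC mouse; each point is 1 mouse. CSF1R and C3 vary little between mice, and CXCL10, ISG15 and IFI44L span more than 1 decade.

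Human and mouse counts of 37 microglia genes were added, an analysis chosen after the data were seen, to ask how total microglial transcripts compared with hCSF1-PBS mice. The median log2 ratio of hFIRE-HPC (n = 4) to hCSF1-PBS (n = 5) was 0.21, a ratio of 1.16, with 23 genes higher and 14 lower. By exact two-sided permutation over 126 arrangements (smallest possible p 0.00794) with adjustment over the 37 genes, 12 were higher and 9 lower. Csf1r totalled 98.9 ± 17.9 and 115 ± 21.3 CPM, 99.8 % of it human in hFIRE-HPC mice (exact permutation adjusted p = 0.346). P2ry12 and Cx3cr1 were 2.97-fold and 2.06-fold higher (exact permutation adjusted p = 0.0173 for each). Ctss stood at 0.179 of the hCSF1-PBS level, and Adgre1, a macrophage adhesion receptor, at 0.0211. Human and mouse orthologs differ in length and mappability, so a single ratio can reflect the species as well as the number of cells.

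In the authors' deposited log2 (VST) values the mouse columns gave the same picture on a compressed scale. Of 35 microglia genes limma called 34 lower in hFIRE-PBS and 34 in hFIRE-HPC than in hCSF1-PBS mice, with medians of -1.54 and -1.75, and 0 between the hFIRE groups (median -0.15). P2ry12 changed by -2.75 (limma adjusted p = 7.67e-14) in hFIRE-PBS and -2.79 in hFIRE-HPC mice, Cx3cr1 by -3.46 and -3.81, and Csf1r by -4.02 and -4.48. Over all genes of that table limma called 86 higher and 265 lower, 162 higher and 305 lower, and 0 and 0 in the 3 comparisons.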

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

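The tests of explanations and the refits over other splits in this part were all chosen only after the results were seen, whereas the rule that singled out mice was fixed beforehand. By that rule a mouse stood apart when its gap to the nearest mouse, as a share of the whole range, passed Dixon's 95% value. Chance alone marks about 1 group in 20, 10.95 of the 219 groups of values examined, and 24 were marked, 12 of them in hCSF1-PBS mouse 5.

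In hCSF1-PBS mouse 5 the list means (log2 CPM) lay far above those of the other hCSF1-PBS mice for interferon response (4.27 against at most 2.12, gap 0.810), complement (4.01 against 2.93, gap 0.954), disease-associated microglia (4.80 against 4.01, gap 0.882), microglia (4.58 against 4.06, gap 0.880), border-associated macrophage (2.06 against 1.34, gap 0.822) and reactive astrocyte genes (3.07 against 2.27, gap 0.899). Irf7, a regulator of interferon genes, measured 47.6 CPM against 1.98 to 3.62 in the others, Lcn2, an acute-phase lipocalin, 18.9 against 0.214 to 1.06, the neutrophil genes S100a8 and S100a9 16.4 and 29.0 against at most 2.99 and 4.28, and Lyz2 82.0 against at most 23.2, with a monocyte and neutrophil list mean of 2.89 against at most 0.854. A library of another group under the wrong label is excluded by Csf1r, at 121 CPM against 78.6 to 99.3 in the other hCSF1-PBS mice and at most 2.43 in hFIRE mice. Blood left in the vessels stays undecided: the erythrocyte mean of mouse 5 differed from the highest of the others by -0.18, within the spread of the group, but Hbb-bs measured 415 CPM against 129 to 334. An inflammatory or antiviral response of this 1 mouse, or more leukocytes in its sample, may explain the values, but infection or injury was not tested and the interferon median of hFIRE-PBS mice turned from -0.59 to 0.27 without it.

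In the same mouse single genes stood apart as well: C1qa (73.0 against at most 39.4 CPM, gap 0.763), C1qb (80.8 against 39.6, gap 0.894), C1qc (64.8 against 34.6, gap 0.847), Ctss (167 against 75.3, gap 0.869) and Gpnmb (2.41 against 1.27, gap 0.755). Excitatory neuron genes were low in it (6.15 against 6.46, gap 0.839).

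Mouse macrophage genes had medians of -1.07 for border-associated macrophages (camera adjusted p = 0.0503 with an estimated correlation) and -0.53 for microglia (0.0498) in hFIRE-HPC against hFIRE-PBS mice. Loss of mouse reads to human orthologs stays open, since only 4 list members had a human gene of the same symbol listed and under 10 CPM (median -1.46, 3 negative), although mouse counterparts of the 200 most abundant other human genes had a median of 0.0866. Less meningeal tissue may account for a part, since the fibroblast list was lower too (camera adjusted p = 0.0498 with an estimated correlation). With all mice it was not enough as the whole cause, since fibroblast genes had a median of -0.36 and their lowest member -0.75. That comparison was not repeated without hFIRE-PBS mouse 4, where the border-associated macrophage median was itself -0.75. No 1 mouse carried the difference, as that median stayed at -0.75 or lower without any mouse. Displacement of mouse macrophages by human cells may explain the difference but was not tested, counts were low, and 3 of 35 splits gave a microglia median as large, so chance stays open.

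Striatal genes had a median of 0.55 in hFIRE-HPC against hFIRE-PBS mice, with 14 of 14 members above 0, no member called by edgeR and a camera adjusted p = 0.0503 with an estimated correlation. More striatal tissue in these hemispheres stays open. The spread of the members (SD 0.117) was close to what error and correlation alone would give (0.114). A common shift of all members through more tissue would leave such a spread. A common shift of expression in striatal neurons would leave it too, so the spread cannot decide between these explanations. Members also correlate by 0.632, so their shared sign does not decide it either. More neurons of any kind explains less, as 32 excitatory and inhibitory genes had a median of 0.062. A change of expression within striatal neurons stays open.

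Other splits of the mice gave 98 or more higher genes in 2 of 100 draws (highest other 113) and 307 or more lower genes in 1, the real one (highest other 131), for hFIRE-PBS against hCSF1-PBS. Chance can be excluded for the lower genes, and for the higher genes only by that share, since 1 other split gave more. It can also be excluded for the microglia median of -3.98 (1 of 100, highest other 2.17 in size) and not for the 17 lists called at the preset (43 of 100, highest other 24). For hFIRE-HPC against hCSF1-PBS chance can be excluded for 190 higher genes only by the share (2 of 100), since 1 other split gave more (207), and for 376 lower genes (1 of 100, highest other 284) and the microglia median of -4.69 (1 of 100, highest other 2.21 in size), and not for the 16 lists (44 of 100, highest other 23). Between the hFIRE groups it cannot be excluded for the microglia median (3 of 35, highest other 0.72 in size) or the 17 lists (4 of 35, highest other 21). For 0 higher, 0 lower and 0 brought back genes the refits decide nothing, since every split gives at least 0 (35 of 35, 35 of 35 and 100 of 100, highest other 1 in each). For the 308 genes called in both hFIRE groups chance can be excluded only as a random grouping of all mice (1 of 100, highest other 0). Those refits shuffled all 3 groups and so broke up the genotype that both hFIRE groups share. They therefore cannot tell whether differences lasted after human cells were given.

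Further mice stood apart in single values. hFIRE-HPC mouse 1 was low in cholesterol efflux genes (5.33 against 5.35, gap 0.841), hFIRE-PBS mouse 1 high in choroid plexus genes (3.32 against 3.04, gap 0.862) and hFIRE-PBS mouse 4 low in TGF-beta and CSF1 receptor ligand genes (3.20 against 3.37, gap 0.872). Rec8 was high in hCSF1-PBS mouse 1 (0.670 against 0.288 CPM, gap 0.715), Krt12 high in hFIRE-PBS mouse 2 (26.1 against 11.4 CPM, gap 0.841) and Eps8l1 low in hFIRE-PBS mouse 4 (3.08 against 3.54 CPM, gap 0.872). Hmga1 was high in hCSF1-PBS mouse 2 (34.7 against 17.1 CPM, gap 0.865) and low in hFIRE-PBS mouse 3 (22.1 against 60.0 CPM, gap 0.896). Csf1 was high in hFIRE-HPC mouse 2 (1.19 against 0.646 CPM, gap 0.949). P2ry13 in hFIRE-HPC mouse 3 (0.114 CPM) and C1qa in hFIRE-HPC mouse 1 (0.0308 CPM) were the only values above 0, with gaps of 1. Human monocyte and neutrophil genes had a higher median in hFIRE-HPC mouse 1 (1.13 against 0.0743 CPM, gap 0.934). The causes of these values were not tested.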

How the results depend on the processing

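The alternatives were chosen before the data were examined, except for the added human and mouse counts and the leaving out of mice for these and for human levels. Counts of called genes depended on the tool, the threshold and single mice. For hFIRE-PBS against hCSF1-PBS the 98 higher genes became 281 with DESeq2, 324 with voom, 34 at an adjusted p of 0.01 and 26 with a log2 change of at least 1, and 48 to 226 without single mice. The 307 lower genes became 468 with DESeq2 and 470 with voom, and 243 to 383 without single mice. For hFIRE-HPC against hCSF1-PBS the 190 higher genes became 431 with DESeq2, 119 in the fit of 2 groups, 57 at 0.01 and 29 with a log2 change of at least 1, and 91 to 274 without single mice, and the 376 lower ones 297 to 437 without single mice. Between the hFIRE groups the counts of 0 and 0 (740 genes at an unadjusted p below 0.05) became 10 and 26 with DESeq2 and stayed 0 and 0 with voom. Leaving out single mice gave 0 higher and up to 7 lower. Of 405 and 566 called genes, voom also called 395 and 482, and fits without a mouse 290 to 388 and 371 to 520. No called gene changed sign in any alternative. DESeq2 size factors moved the share of higher calls only from 24.2 to 24.1 % and from 33.6 to 35.1 %.

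Genes called in both hFIRE groups numbered 308, 482 with DESeq2, 203 with split hCSF1-PBS mice and 248 to 408 without single mice. Genes brought back numbered 0, 4 with DESeq2 and 0 without any single mouse. Of 40 genes with the largest changes, 33 to 38 kept their calls without single mice.

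Microglia medians were -4.11 to -3.86, -4.85 to -4.44 and -0.68 to -0.44 without single mice in the 3 comparisons, and the third, -0.53, was -0.41 in the fit of 2 groups. List calls numbered 50, 5 with an estimated correlation, 17 with fry and 41 to 56 without single mice. The interferon median of hFIRE-PBS mice, -0.59, turned to 0.27 without hCSF1-PBS mouse 5, was -0.84 without hCSF1-PBS mouse 4, and turned to 0.25 with the replicate block, which leaves out that mouse's own information since no other group has a mouse 5.

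The human share of 3.16 % became 3.40 % without mitochondrial genes, 3.26 % without the 10 most abundant genes and 2.75 to 3.35 % without single mice. The human microglia median of 814 CPM became 26.0 CPM of both species together, by the change of denominator, and 789 to 841 without single mice. In VST values the medians of -1.54, -1.75 and -0.15 became -3.98, -4.69 and -0.53 with edgeR on counts and -1.10, -1.20 and -0.10 without the lowest quartile, where 12 and 12 members were called, and -1.60 to -1.48, -1.79 to -1.69 and -0.19 to -0.13 without single mice. The added human and mouse counts, with a median ratio of 0.21 on the log2 scale, gave 0.09 to 0.31 without single mice.

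The replicate block was run because the groups share numbers. Of 12 same-numbered pairs 5 correlated above 0.1 and 4 above every other pairing (-0.285 to 0.243), so the numbers do not pair the mice. With the block 313 of 405 and 400 of 566 calls were made again, the 190 higher genes became 126, and VST medians were -1.48 and -1.69.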

Other observations

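The genes from Hspa8 to Oscar and the tests of neighbouring genes were chosen only after the values were seen. These single genes were higher in both hFIRE groups than in hCSF1-PBS mice, and no group of genes was tested. Hspa8, the constitutive chaperone of clathrin uncoating and chaperone-mediated autophagy, measured 677 ± 120, 1419 ± 238 and 1542 ± 167 CPM (log2 1.07 and 1.19, edgeR adjusted p = 0.000115 and 2.88e-05). Atp6v0c, a subunit of the lysosomal proton pump, rose from 426 to 658 and 639 CPM (log2 0.63 and 0.58, edgeR adjusted p = 0.0242 and 0.0318). Dgat2, which makes triglycerides for lipid droplets, rose from 35.2 to 51.1 and 53.0 CPM (log2 0.54 and 0.59, edgeR adjusted p = 0.0179 and 0.00737), and Odc1, the first enzyme of polyamine synthesis, by 0.61 and 0.58 (edgeR adjusted p = 0.00456 and 0.00657). Cx3cl1, the neuronal ligand of the microglial receptor Cx3cr1, rose from 288 to 422 and 407 CPM (log2 0.55 and 0.50, edgeR adjusted p = 0.0299 and 0.0443). Nupr1, a stress-induced chromatin factor, rose by 0.80 and 0.97 (edgeR adjusted p = 0.0243 and 0.00486), and Flnc, an actin cross-linker, by 1.07 and 0.97 (edgeR adjusted p = 0.00149 and 0.00329). Oscar, a collagen receptor of osteoclasts and myeloid cells, rose from 0.129 to 1.21 and 0.767 CPM while most other myeloid genes fell (log2 3.19 and 2.55, edgeR adjusted p = 3.80e-06 and 5.28e-05). The share of these genes that depends on single mice was not examined.

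Of 51 genes higher in both hFIRE groups and outside the myeloid lists, 7 had another within 3 tested genes, against a median of 0 and at most 4 in the central 95% of 10000 random draws (permutation p = 0.0008). Of these, 5 were next to genes of the same family only, as Alox8 to Alox12b and Krt12 to Krt20 and Krt23, whose reads can be shared, and the other 2, Clmp and Hspa8, are within what random draws gave. Near Csf1r lay only Aldh7a1 within 50 tested genes (permutation p = 0.264). Gm10548, Pcdhgb2, Pcdhga11 and Mcc, also on its chromosome 18, lay outside that window, and the remaining genes lay on other chromosomes. A longer stretch around Csf1r was not tested. Only genes called higher were examined, and only within these windows, so other differences linked to the genotype are not excluded.

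Serpina3n, an acute-phase protease inhibitor of reactive astrocytes, measured 29.2, 52.4 and 83.5 ± 54.0 CPM without a call (hFIRE-HPC against hCSF1-PBS log2 1.51, edgeR adjusted p = 0.135). Lyz2, the lysozyme of myeloid cells, measured 31.7 ± 28.2, 23 ± 26.0 and 2.88 ± 1.17 CPM (hFIRE-HPC against hCSF1-PBS log2 -3.47, edgeR adjusted p = 0.0601), with 82.0 CPM in hCSF1-PBS mouse 5 against 16.1 to 23.2 in the other hCSF1-PBS mice. The human gene SIGLEC1, an interferon-induced receptor of border macrophages, measured 13.6, 320, 50.9 and 399 CPM in hFIRE-HPC mice 1 to 4.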
